A study of Mus musculus with 4 samples.

How the data were processed

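The gene and peak tables hold counts, deposited by the authors as UMIs per gene and nucleus and as counts per peak and nucleus, made against mm10. The authors' notes name FastQC, Cell Ranger, Cell Ranger ARC, Seurat and Signac, whose versions and order are not given in the sources used here. Peaks were called by library as deposited, since the peak names differ between the libraries. In the authors' deposited table, the baseMean column is a signal, the mean of counts divided by size factors per the file headers. The log2 fold changes of that table are log2 ratios made by the authors with DESeq2, per the file headers, and their direction was read against the counts. The p-values and adjusted p-values of that table come from the DESeq2 Wald test, per the file headers, and 13 of its 10156 gene names had been turned into dates and were not matched. What the number in the name of that table stands for, and which nuclei entered it, are not given in the sources used here.

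The lists, filters, comparisons and rule for naming genes were fixed before the data were examined. Nuclei with at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs were kept, which removed 110 Sun1_WT and 232 Sun1_KO nuclei. Scrublet, as run in scanpy, called 0 and 2 doublets, below the 0.5% set as the least for a working call, and no nucleus was removed for it. Both expression libraries were clustered together, without integration, on 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 with seed 0. A cluster was named tumour-cell-like when its summed fixed tumour markers reached 1000 CPM, at least 3 of them were detected and at most 1 marker of another class was among its 40 leading genes. Below 1000 CPM it took the class with most markers, at least 3, among the leading genes. Clusters with a median depth far below that of their library were held to stricter terms. These thresholds were set after seeing the data. No other class had 50 nuclei in each library. Macrophage-like, NK-cell-like and T-cell-like names describe markers and not proven identities.

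Counts of each class and library were summed and divided by the total without mitochondrial genes, and genes with at least 100 summed UMIs were compared as log2 ratios after adding 0.5. Intervals were exact Poisson for sums, exact binomial for shares and exact conditional binomial for ratios. A ratio with a count of 0 was given as a bound against a floor of 3. The 35 gene lists were used in a class where at least 5 members were measured, which gave 35, 30, 15 and 10 lists in tumour-cell-like, macrophage-like, NK-cell-like and T-cell-like nuclei. The list median was placed among 10000 random lists of the same size, matched on expression in 20 bins. Named genes were the targeted gene, the 10 higher and 10 lower genes with the largest ratio by the interval bound nearest 1 (5 and 5 in NK-cell-like nuclei), without mitochondrial genes and unnamed gene models, and up to 2 highest and 2 lowest members of each list. Named peaks were the 5 higher and 5 lower by the same bound.

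Peaks of the accessibility libraries that overlapped by at least 1 bp were merged to regions, and classes were carried over by barcode. Regions were assigned to genes within 1 kb of either gene end. The plan had been to use transcription start sites, but the annotation used (GRCm38.p6) gives no strand. With starts below 3 Mb of a chromosome left out, it placed 26266 of 32285 genes (81.4%).

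The work was done with Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, igraph 0.11.9 and matplotlib 3.10.9. TMM factors came from edgeR 4.0.16 in R 4.3.3, used for nothing else. Alternatives were TMM and median-ratio scaling, mitochondrial genes in the total, other UMI minimums, a pseudocount of 5, thinning to 1000 UMIs, other clusterings, other nucleus filters, binarised accessibility and a stricter peak overlap, 22 planned and 10 added.

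Chosen after seeing the data were the stretches of chromosomes X and 15, the window threshold of 0.3, the boundary of 3000 CPM, the genes whose loci or shares of nuclei are given, the joining of the Dcn clusters to the tumour-cell-like class, the filters on Hmga2 and on doublet score, the removal of single nuclei, the clustering without defining genes and the use of both gene ends. The median of the cytotoxic list without 1 nucleus and that of the lower genes outside the X stretch were also taken after seeing the data. Nsd1, Gzmc and Prf1 were likewise chosen after their values were seen.

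The method was tried on simulated pairs, made by Poisson draws from the pooled counts of a class with 200 genes changed 2-fold or 4-fold. Such draws hold no spread beyond counting error and follow the model of the intervals. Coverage near 95% was therefore built in and does not show coverage in the real libraries. In the tumour-cell-like pair (12453 genes) all changed genes had the right direction, and the interval covered the true ratio for 99.0%, 94.8% and 95.3% of genes changed 2-fold, changed 4-fold and unchanged. The same shares were 92.9%, 95.2% and 95.5% in macrophage-like (6168 genes), 96.3%, 92.1% and 94.9% in NK-cell-like (1426 genes), and 93.9%, 95.7% and 94.9% in T-cell-like nuclei (982 genes). In accessibility they were 96.0%, 93.9% and 95.5% in tumour-cell-like (108038 regions) and 93.9%, 91.5% and 95.7% in macrophage-like nuclei (36613 regions). A list shifted by -0.5 came back at -0.51, -0.51, -0.53 and -0.60 over 12481, 6196, 1454 and 1010 genes in tumour-cell-like, macrophage-like, NK-cell-like and T-cell-like nuclei, while 3 of 34, 1 of 29, 0 of 13 and 0 of 9 unshifted lists lay in the outer 5% of random lists.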

Results

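CT26 cells, a colon carcinoma line of BALB/c mice, were grown under the skin of syngeneic mice, and the tumours were taken on day 14. The injected cells either carried Sun1 intact (Sun1_WT) or had it knocked out (Sun1_KO). Sun1 encodes a protein of the inner nuclear membrane and part of the LINC complex, which links the nuclear lamina to the cytoskeleton. The kit used reads RNA and open chromatin from the same nucleus, so each genotype gave 1 expression library and 1 accessibility library, 4 libraries in all. The Sun1_WT expression library held 3455 nuclei with 53707675 unique molecular identifiers (UMIs, counted RNA molecules) and a median of 13789 per nucleus. The Sun1_KO library held 2404 nuclei with 35471291 UMIs and a median of 11548.5. In the accessibility libraries, 227006096 counts in 127147 peaks were recorded for Sun1_WT and 183750142 counts in 134365 peaks for Sun1_KO, with medians of 63898 and 61604 per nucleus. After filtering, 3345 Sun1_WT and 2172 Sun1_KO nuclei were compared. There were no replicates, so no test between the genotypes was possible. All intervals are 95% intervals for counting error only, and counts of genes or regions past 2-fold are counts by size. Even numbers made up 75.46% and 74.98% of recorded values in the Sun1_WT and Sun1_KO accessibility libraries, against 33.02% and 32.91% in expression. Accessibility counts were thus largely not independent single counts. The accessibility intervals treat them as independent, so these intervals are probably too narrow even for counting error. Every log2 ratio is Sun1_KO over Sun1_WT.

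Sun1 itself, on chromosome 5 from 139200564 to 139249839 (mm10), was lower in Sun1_KO tumour-cell-like nuclei. It stood at 108 CPM (counts scaled by the total of the class; 105 to 111, 4011 UMIs) in Sun1_WT and 65.5 CPM (62.0 to 69.2, 1287 UMIs) in Sun1_KO, a log2 ratio of -0.72 (-0.81 to -0.63). In host cells, which were not edited, the ratio was 0.24 (-0.27 to 0.74) in macrophage-like, 0.21 (-1.14 to 1.55) in NK-cell-like and 0.70 (-0.51 to 2.15) in T-cell-like nuclei, so no difference was detectable there at this depth, and the macrophage-like ratio was -0.40 after thinning to 1000 UMIs. At least 1 Sun1 UMI was found in 79.3% of Sun1_WT and 61.4% of Sun1_KO tumour-cell-like nuclei, at median depths of 18764 and 17589 UMIs. The same shares were 15.8% and 15.3% in macrophage-like nuclei, at 4659 and 4448.5 UMIs. The 3 shared accessible regions over the gene were about equally open, with a log2 ratio of -0.04 in tumour-cell-like and 0.01 in macrophage-like nuclei. Which part of Sun1 was deleted is not given in the sources used here, and a count from a part of the transcript outside the deletion checks nothing about the knockout.

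The first comparison concerned the makeup of the tumours. Macrophage-like nuclei, marked by Lyz2, C1qa and Mrc1, formed a larger part of the Sun1_KO tumour, at 15.7% (14.1 to 17.3) against 10.6% (9.59 to 11.7) of nuclei. T-cell-like nuclei, marked by Themis, Cd3e and Cd8a, made up 3.08% (2.40 to 3.90) against 1.76% (1.35 to 2.27). Tumour-cell-like nuclei made up 48.8% (46.6 to 50.9) of Sun1_KO and 57.9% (56.2 to 59.6) of Sun1_WT nuclei. Because genes that define these clusters also differed between the libraries, the nuclei were clustered again without the fixed markers and the leading genes of the named clusters. The Sun1_KO to Sun1_WT ratio of shares was then 1.47 (1.26 to 1.72) for macrophage-like, 1.88 (1.29 to 2.73) for T-cell-like and 0.809 (0.7505 to 0.871) for tumour-cell-like nuclei. NK-cell-like nuclei, which carry cytotoxic granules, made up 5.62% (4.69 to 6.67) of Sun1_KO and 3.20% (2.63 to 3.85) of Sun1_WT nuclei in the first clustering. They had no named cluster of their own in the clustering without those genes. A cluster with 5 NK markers among its 40 leading genes, but also with tumour markers, held 8.66% (7.51 to 9.92) of Sun1_KO and 5.08% (4.36 to 5.88) of Sun1_WT nuclei. It took in 121 of 122 and 107 of 107 of the nuclei otherwise called NK-cell-like. Neutrophil-like nuclei numbered 14 in Sun1_WT and 6 in Sun1_KO.

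Unnamed clusters took 26.1% of Sun1_WT and 26.6% of Sun1_KO nuclei. Of these, clusters with Dcn, a proteoglycan of fibroblasts, together with the tumour gene Hmga2 held 17.8% and 13.2%. Clusters in which tumour genes stood beside leukocyte genes held 4.36% and 8.61%. In Sun1_KO, Dcn clusters 1 and 12 had median accessibility shares of 2160 and 2164 CPM in the X stretch described below. Sun1_KO tumour-cell-like nuclei had 2162 and macrophage-like nuclei 4073 CPM. Over both libraries, Xist was at 1.39 and 4.19 CPM in these clusters and 1624 CPM in the macrophage-like cluster. These values argue against host cells for the Sun1_KO nuclei of the Dcn clusters. In Sun1_WT the stretch cannot decide, with 4391 and 4365 CPM in these clusters beside 4209 in tumour-cell-like and 3993 in macrophage-like nuclei. The tumour-cell-like shares given above leave the Dcn clusters out. With them the class held 2535 of 3345 Sun1_WT and 1345 of 2172 Sun1_KO nuclei. As first named, the tumour-cell-like class was made of different clusters in the libraries. Clusters 6, 2, 0, 7 and 3 held 23.9%, 19.9%, 16.5%, 16.3% and 13.3% of it in Sun1_WT, and clusters 11 and 17 held 35.8% and 30.1% of it in Sun1_KO. The macrophage-, NK- and T-cell-like classes were each 1 cluster. The lower tumour-cell-like share changed when nuclei were filtered and then clustered and named again. The ratio was 0.978 over nuclei with at least 1500 UMIs and 1.07 without the 5% of nuclei with the highest doublet scores, an alternative chosen after seeing the data. Within the class as first named, the first filter kept 1919 of 1938 Sun1_WT and 1041 of 1059 Sun1_KO nuclei, and the second 1885 and 1041. The new class assignment, and not the filter alone, thus entered these ratios. The macrophage-like ratio was 1.49 and 1.63 in those runs with newly named classes, and the T-cell-like ratio 2.33 and 1.76.

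**Figure D1:**
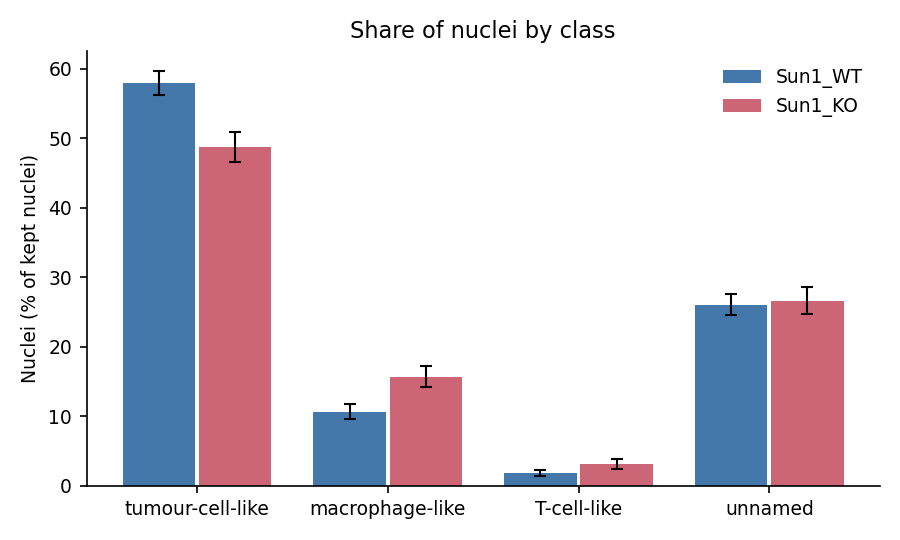
Share of kept nuclei (%, y axis) in the tumour-cell-like, macrophage-like and T-cell-like classes and in unnamed clusters (x axis) for the Sun1_WT library (3345 nuclei) and the Sun1_KO library (2172 nuclei), with exact binomial 95% intervals for counting error only. NK-cell-like and neutrophil-like nuclei are not drawn, and clusters with both Dcn and Hmga2 count as unnamed. Macrophage-like nuclei stand at 10.6% and 15.7%, and tumour-cell-like nuclei at 57.9% and 48.8%. The tumour-cell-like ratio passes 1 when nuclei with the highest doublet scores are left out and the rest are clustered and named again.

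In tumour-cell-like nuclei, several genes were nearly silent in Sun1_KO. Cask, a membrane scaffold kinase on chromosome X (13517080 to 13846783), had 1979 UMIs in Sun1_WT and 9 in Sun1_KO, a log2 ratio of -6.78 (-7.99 to -5.93). Tmlhe, the first enzyme of carnitine synthesis, had 1451 and 11 UMIs (-6.06, -7.13 to -5.28), and Il13ra1, a receptor subunit for interleukin 13 on chromosome X (36112108 to 36171262), had 461 and 4 (-5.76, -7.81 to -4.56). Krt18, a keratin of simple epithelia on chromosome 15 (102028216 to 102032026), had 271 and 1 UMIs, a ratio of 0.00698 (0.000176 to 0.0392). The palmitoyltransferase gene Zdhhc15 (-5.22), the kinase gene Prkx (-4.25), the zinc-finger gene Zfp978 (-4.21, uncertain because of near-identical relatives) and the aldehyde dehydrogenase gene Aldh3a1 (-4.03) were also among the 10 lowest. Aldh5a1, which clears succinate semialdehyde, had 105 UMIs in Sun1_WT and 0 in Sun1_KO and was at least 18.5-fold lower against a floor of 3 counts. Gnasas1, an antisense transcript of the Gnas locus, had 186 and 1 UMIs, a ratio of 0.0102 (0.000256 to 0.0573), and the use of strand in its counting is not given in the sources used here. Of these 10 genes, Cask, Il13ra1, Zdhhc15 and Prkx lie on chromosome X in the annotation. Tmlhe was given no position, since genes absent from the annotation or starting below 3 Mb of a chromosome were left unplaced. It may thus also lie on chromosome X.

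Other genes were far higher in Sun1_KO tumour-cell-like nuclei. Ift81, a subunit of the intraflagellar transport machinery of cilia on chromosome 5 (122540265 to 122614546), had 1405 UMIs in Sun1_WT and 5578 in Sun1_KO, a log2 ratio of 2.91 (2.82 to 2.99). It was found in 44.6% and 94.0% of tumour-cell-like nuclei, against 4.23% and 8.53% of macrophage-like nuclei, at median depths of 18764, 17589, 4659 and 4448.5 UMIs. Ikzf2, which encodes the transcription factor Helios, had 78 and 597 UMIs (3.85, 3.51 to 4.21), and Eomes, a T-box factor of lymphocytes, had 17 and 133 (3.85, 3.15 to 4.71). Fmn2, an actin-nucleating formin, had 3 and 100 UMIs, a ratio of 63.0 (21.0 to 311). Arhgap15, a Rac regulator of leukocytes, stood at 2.93 (2.69 to 3.18), with the potassium channel subunit gene Kcnab2 at 2.54, the rhomboid protease gene Rhbdl2 at 2.72, the metalloprotease gene Adamts12 at 2.37 and the neuronal adhesion genes Mdga2 and Lrfn5 at 2.71 and 2.57. The leukocyte gene Ptprc, with 93 and 192 UMIs, was also higher in tumour-cell-like nuclei (1.96, 1.60 to 2.34), at 9.77 CPM in Sun1_KO beside 1520 CPM in macrophage-like nuclei. When the class was built without its defining genes, Ift81 stood at 2.90, and all other named genes of the class kept their side and size.

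**Figure D2:**
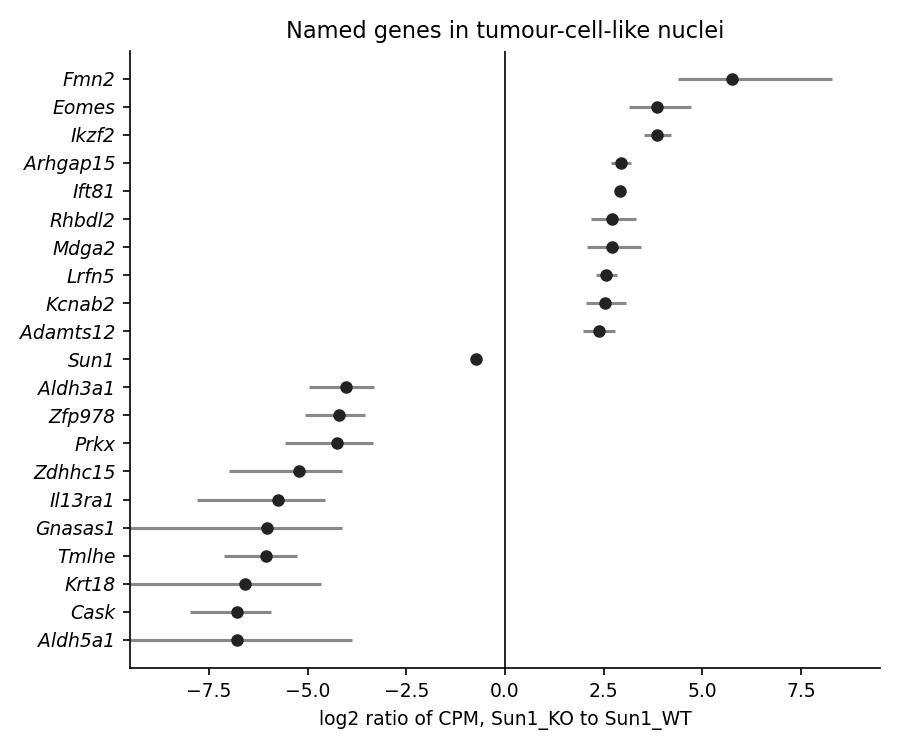
Log2 ratio of Sun1_KO to Sun1_WT (x axis) for Sun1 and the named highest and lowest genes (y axis) in tumour-cell-like nuclei (1938 Sun1_WT and 1059 Sun1_KO nuclei), with exact 95% intervals for counting error only. Sun1 lies at -0.72, Ift81 at 2.91 and Cask at -6.78, while Aldh5a1 has 0 UMIs in Sun1_KO and only a bound.

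Among the gene lists fixed beforehand, hypoxia and glycolysis genes were lower in Sun1_KO tumour-cell-like nuclei, and targets of the growth regulators YAP and TEAD were higher. Of 26 measured hypoxia and glycolysis genes, 10 were at least 1.5-fold lower and 2 at least 1.5-fold higher, with a median of -0.50, below all 10000 random lists matched on expression (percentile 0). Ankrd37 (-1.35) and Ndrg1 (-1.04), both induced by low oxygen, were among the lowest, while the carbonic anhydrase gene Car9 (0.94, but -0.30 after thinning to 1000 UMIs) and the phosphofructokinase gene Pfkp (0.80) were higher. Ndrg1, Ankrd37, Bnip3 and Slc2a1 are among the leading genes of cluster 6, which held 464 of 1938 nuclei of the class in Sun1_WT and 116 of 1059 in Sun1_KO. Of 19 YAP and TEAD targets, 6 were at least 1.5-fold higher and 0 lower, with a median of 0.36 (percentile 98.4), which was 0.14 with TMM scaling. The matricellular genes Ccn1 and Ccn2 stood at 1.58 and 1.52, with 1937 and 3062 UMIs of Ccn1. Genes of the unfolded protein and integrated stress response had a median of -0.26 over 19 genes (percentile 0.14), with the asparagine synthetase gene Asns at -1.04 and the lipoprotein receptor gene Vldlr at -0.75. Its member Sesn2, also a p53 target, was at 0.63.

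Of 19 genes of MHC class I presentation, 14 lay within 1.5-fold, 4 were lower and 1 higher, with a median of -0.06 (percentile 8.02), which was 0.0016 after thinning and -0.27 with TMM scaling. The non-classical class I gene H2-T23, uncertain because it has near-identical relatives, was at -1.85 and the immunoproteasome gene Psmb9 at -0.79, while the class I transactivator Nlrc5 was at 0.68 and the peptide transporter gene Tap1 at 0.29. For MHC class II presentation, the median over 7 genes was -0.46 (percentile 0.66), but 0.205 against only the low-share Sun1_WT nuclei described below, with the transactivator Ciita at -1.57 and H2-DMb1 at -1.51. Of 22 interferon gamma response genes, 4 were at least 1.5-fold higher, including Fgl2 at 1.94, and 2 lower, with a median of 0.29 (percentile 92.6), which was 0.07 with TMM scaling. Type I interferon-stimulated genes had a median of 0.05 over 31 genes, with the ubiquitin-like modifier Isg15 at -0.76 and the signal transducer Stat2 at 0.66, and this median was -0.17 with TMM, -0.09 with median-ratio scaling and -0.02 with mitochondrial genes in the total. The chemokine gene Ccl2, which draws monocytes, was at 78.6 CPM in Sun1_WT and 7.07 CPM in Sun1_KO (-3.47, -3.73 to -3.23), while the cytokine gene Lif (1.01) and the neutrophil chemokine gene Cxcl1 (1.05) of the same NF-kB list were higher. Of 14 measured genes in that list, 3 were at least 1.5-fold higher and 3 lower, with a median of 0.22, which was -0.0017 with TMM scaling. Of 14 checkpoint ligands and receptors, 11 lay within 1.5-fold, 2 were higher and 1 lower, with a median of 0.18 (percentile 62.4), which was -0.039 with TMM scaling and -0.053 after thinning. The adhesion receptor gene Ceacam1 was at -2.92, the do-not-eat-me signal gene Cd47 at -0.46 and the NKG2D ligand gene Ulbp1 at 0.65.

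Genes of the nuclear envelope, the compartment of the Sun1 protein, moved little in RNA as a group. Of 20 genes, 18 lay within 1.5-fold, 1 was higher (Lemd3, 0.86) and 1 lower (Sun1). The nuclear pore gene Nup153 was at 0.53 and the chromatin-bridging gene Banf1 at -0.54. Accessibility over the list member Sun2 (chromosome 15, 79724068 to 79742536) was at -0.44 (-0.48 to -0.39), beside 0.10 in macrophage-like nuclei. This locus was chosen after seeing the data. The list median was 0.05, and it was -0.17 with TMM, -0.09 with median-ratio scaling and -0.02 with mitochondrial genes in the total. S phase genes had a median of -0.06 over 40 genes (percentile 0.60), which was 0.038 after thinning, -0.28 with TMM and -0.20 with median-ratio scaling, with Gins2 at -0.73, Gmnn at -0.62 and E2f8 at 0.53. Of 16 p53 targets, 5 were at least 1.5-fold higher, such as the RNA-binding gene Zmat3 at 0.79, and 1 lower, Phlda3 at -0.69, with a median of 0.27, which was 0.05 with TMM scaling. Mesenchymal genes had a median of 0.0017 over 22 genes, and of -0.22 with TMM and -0.13 with median-ratio scaling. Of these genes, 11 were above and 11 below 0, with 2 at least 1.5-fold higher and 4 lower, among them the matrix genes Tnc (-1.49) and Sparc (-1.03).

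All 28 ribosomal protein genes were below 0 in Sun1_KO tumour-cell-like nuclei, 18 of them at least 1.5-fold, with a median of -0.75 (percentile 0), Rpl10 at -1.45 and Rps3 at -1.29. Single ribosomal protein genes are uncertain, since many have near-identical processed copies. In the same nuclei the mitochondrial share of UMIs was 7.08% in Sun1_WT and 11.5% in Sun1_KO. The mitochondrial share differed in the same way in the other classes, beside every gene group given below.

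Over all 12511 genes compared in tumour-cell-like nuclei, 287 were at least 2-fold higher and 356 at least 2-fold lower in Sun1_KO, and 94.9% lay within 2-fold. The median gene was at 0.14, and TMM scaling moved it by over 0.1 to -0.08, median-ratio scaling to 0. These scalings changed the balance of higher to lower genes from 44.6% higher to 17.5% (144 higher, 681 lower) and 25.8% (186 higher, 536 lower), and keeping mitochondrial genes in the total gave 33.3% (222 higher, 444 lower).

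In macrophage-like nuclei, genes of phagocytosis and complement were lower in Sun1_KO and interferon gamma response genes were higher. Of 20 genes of phagocytosis and complement, 8 were at least 1.5-fold lower and 0 higher, with a median of -0.43 (percentile 0). The lipid receptor gene Trem2 had 237 and 108 UMIs, the lysosomal glycoprotein gene Cd68 stood at -0.88 and the cathepsin gene Ctsl at -0.85. Of 22 interferon gamma response genes, 5 were at least 1.5-fold higher and 0 lower, with a median of 0.39 (percentile 100), the immunity-related GTPase gene Irgm1 at 0.90 and Ciita at 0.77. Lyz2, which encodes lysozyme, was at 4254 CPM in Sun1_WT and 1887 CPM in Sun1_KO (-1.17, -1.23 to -1.11), and the macrophage elastase gene Mmp12 at 526 and 135 CPM (-1.96, -2.18 to -1.76). The lipopolysaccharide co-receptor gene Cd14 was at -1.21 (-1.39 to -1.03) and the platelet factor gene Pf4 at -1.52 (-1.94 to -1.13). Lyz2, Cd68 and Trem2 are among the markers of this class, and without the defining genes in the clustering they stood at -1.17, -0.89 and -1.03.

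For MHC class II presentation, the median over 8 genes in macrophage-like nuclei was 0.29 (percentile 98.8), with H2-DMb1 at 0.62, H2-DMa at -0.66 and the invariant chain gene Cd74 at -0.34. It was 0.20 with TMM scaling (-0.0042 to 0.27) and with median-ratio scaling (-0.0021 to 0.27), and 0.095 (0.019 to 0.17) over nuclei with no Hmga2 UMI, a filter chosen after seeing the data. Of 17 heterochromatin genes, 16 were above 0 and 2 at least 1.5-fold higher, with a median of 0.32 (percentile 99.8), Cbx5 at 0.68 and Uhrf1 at 0.88. G2/M genes had a median of 0.26 over 41 genes (percentile 99.7), 6 of them at least 1.5-fold higher, and of 0.11 (-0.036 to 0.19) over nuclei with no Hmga2 UMI. Genes of cholesterol and fatty acid synthesis had a median of 0.33 over 11 genes (percentile 97.8), with the desaturase gene Scd2 at 0.73 and the carboxylase gene Acaca at 0.68. Type I interferon-stimulated genes had a median of 0.20 over 30 genes (percentile 96.4), and all 30 lay within 1.5-fold. Over nuclei with no Hmga2 UMI it was 0.34. The pro-inflammatory list had a median of 0.07 over 14 genes, and -0.02 with TMM or median-ratio scaling, and it was also below 0 over genes with at least 500 UMIs. Its members went both ways, with the cyclooxygenase gene Ptgs2 at 1.07 and Il1rn at 0.63, and the nitric oxide synthase gene Nos2 at -0.87 and Il1b at -0.45. Tissue-repair genes had a median of -0.09 over 18 genes, 5 of them at least 1.5-fold lower, and of -0.21 over nuclei with no Hmga2 UMI. Hypoxia and glycolysis genes had a median of -0.14 over 20 genes (percentile 0.31), with Vegfa at -0.62, and all 28 ribosomal protein genes were below 0, with a median of -0.46 (percentile 0.04). The tumour gene Hmga2, a measure of RNA from tumour cells in this class, was at 84.7 CPM in Sun1_WT and 226 CPM in Sun1_KO, and the mitochondrial share at 5.69% and 9.64%.

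Taco1, a mitochondrial translation factor gene, was the highest named gene in macrophage-like nuclei, with 18 and 126 UMIs (2.91, 2.22 to 3.74). The phagocytic receptor gene Timd4 was at 1.76 (1.17 to 2.43) and the interleukin 18 receptor subunit gene Il18rap at 1.54 (0.91 to 2.24). A single Sun1_KO nucleus of 65678 UMIs held 70.4% of the Slit3 UMIs and 47.7% of the Hmga2 UMIs of its class. Without the nucleus with most UMIs of the gene in each library, Slit3 went from 1.47 to 0.27 and Hmga2 from 1.41 to 1.27, and over nuclei with no Hmga2 UMI Slit3 stood at -0.74. Likewise 1 Sun1_WT nucleus held 179 of the 192 UMIs of the globin gene Hbb-bs, and the ratio went from -5.29 to -1.81 without it, while Gzmb, a granzyme of lymphocytes, went from -2.37 to -1.79. Over 6210 genes, 43 were at least 2-fold higher and 57 at least 2-fold lower, which is 43.0% higher. With TMM or with median-ratio scaling 29 were higher and 79 lower (26.9% higher), and with mitochondrial genes in the total 31 and 72 (30.1%).

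In NK-cell-like nuclei, the granzyme genes Gzma and Gzmb were lower in Sun1_KO. Gzma, which encodes granzyme A, was at 6091 CPM in Sun1_WT and 1262 CPM in Sun1_KO (-2.27, -2.43 to -2.11) and Gzmb at 2943 and 814 CPM (-1.85, -2.06 to -1.65). The interferon-induced membrane protein genes Ifitm2 and Ifitm1 stood at -2.84 (-3.62 to -2.20) and -2.63 (-3.69 to -1.81), and Tyrobp, the signalling adaptor of activating receptors, at -1.77 (-2.15 to -1.42). Gzma, Gzmb and other granzymes are among the leading genes of this cluster. In the cluster found without the defining genes, Gzma was at -2.08 (-2.21 to -1.94), Gzmb at -1.60 (-1.77 to -1.43), Ifitm2 at -1.29 and Tyrobp at -1.16. Granzymes D, E, F and G were higher in the sums (Gzmg 7.81, Gzme 3.86, Gzmd 3.64, Gzmf 2.16), but 1 Sun1_KO nucleus held 3543 of their 3562 UMIs. Without that nucleus, but with all Sun1_WT nuclei kept, Gzmd stood at -2.55 (-3.48 to -1.81), Gzme at -2.66 (-5.22 to -1.15) and Gzmf at -6.99 (-12.89 to -5.08). Gzmg then had 0 UMIs in Sun1_KO and 5 in Sun1_WT, too few for a direction. These 4 genes are near-identical, so how reads were divided among them is uncertain. The same nucleus held 51.9% of the Gzmc and 48.1% of the Prf1 UMIs of the class, 2 genes chosen after their values were seen, and without the nucleus with most UMIs of each gene Gzmc went from -1.36 to -1.94 and Prf1, which encodes perforin, from -0.51 to -1.23.

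Of 14 cytotoxic effector genes in NK-cell-like nuclei, 5 were at least 1.5-fold lower and 3 higher, with a median of -0.39 (percentile 7.60), and those 3 were Gzmd, Gzme and Gzmf. Without the 1 Sun1_KO nucleus that held nearly all their UMIs, 8 of 13 measured members were at least 1.5-fold lower and 0 higher, with a median of -1.34 (percentile 0). All Sun1_WT nuclei were kept there, so leaving out this nucleus lowered the ratios of the genes it was rich in by construction. That median therefore lends no support to lower cytotoxic RNA. In Sun1_WT the UMIs of granzymes D to G lay in 15 of 107 nuclei. All 7 hypoxia and glycolysis genes were below 0, with a median of -0.70 (percentile 0.065), the enolase gene Eno1 at -1.22 and Gapdh at -0.72. G2/M genes had a median of -0.36 over 9 genes (percentile 1.45), with the proliferation gene Mki67 at -1.06 and Top2a at -0.54. The interferon gamma response list had a median of 0.37 over 6 genes (percentile 94.4), 2 of them at least 1.5-fold higher, with Nlrc5 at 1.04 and Gbp7 at 0.86. The type I list had a median of 0.39 over 8 genes (percentile 94.4), 2 of them at least 1.5-fold higher, with Herc6 at 0.84 and Parp14 at 0.82. In the cluster found without the defining genes these were smaller, with Nlrc5 at 0.38, Gbp7 at 0.07, Herc6 at 0.27, Parp14 at 0.37 and Mki67 at -0.31. All 28 ribosomal protein genes were below 0, with a median of -0.75 (percentile 0.10) and Rpl10 at -1.60, while the mitochondrial share was 3.48% and 7.91%. The sialyltransferase gene St6galnac3 was at 1.34 (0.94 to 1.77). Over 1486 genes with a median of 0.10, 34 were at least 2-fold higher and 52 lower, which is 39.5% higher, against 26.6% (25 and 69) with TMM, 22.9% (22 and 74) with median-ratio scaling and 29.0% (27 and 66) with mitochondrial genes in the total.

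In T-cell-like nuclei, Cxcr6, Nkg7, Gzmb and Id2 were lower in Sun1_KO and the memory-associated repressor gene Bach2 was higher. Cxcr6, a chemokine receptor of resident and effector T cells, was at -1.31 (-1.73 to -0.91), the granule protein gene Nkg7 at -1.15 (-1.53 to -0.79), Gzmb at -1.14 (-1.53 to -0.76) and the transcriptional regulator gene Id2 at -1.24 (-1.58 to -0.92). Bach2 was at 1.11 (0.75 to 1.49) and Cmss1, a gene with a role in ribosome assembly, at 1.92 (1.44 to 2.47), with 39 and 211 UMIs. Of 10 cytotoxic effector genes, 9 were below 0 and 3 at least 1.5-fold lower, with a median of -0.42 (percentile 0.23). Exhaustion and activation genes had a median of -0.25 over 9 genes, 4 of them at least 1.5-fold lower, which was 0.03 over nuclei with no Hmga2 UMI, with the inhibitory receptor gene Havcr2 at -1.13, the nuclear receptor gene Nr4a2 at 0.58 and the exhaustion regulator gene Tox at 0.39. Heat shock and immediate early genes had a median of 0.61 over 5 genes (percentile 99.2), with the chaperone genes Hspa1b at 1.14 and Hspd1 at 1.00. G2/M genes had a median of 0.35 over 8 genes (percentile 97.9), with the microtubule gene Ckap5 at 1.11. Hypoxia and glycolysis genes had a median of -0.28 over 7 genes (percentile 2.62), all 7 below 0 before thinning, with Gapdh and Eno1 both at -0.76 and Eno1 at 0.33 after thinning to 1000 UMIs. Of 28 ribosomal protein genes, 24 were below 0, with a median of -0.31 (percentile 9.62), Rpl10 at -1.09 and Rpl3 at 0.39 (-0.028 after thinning), while the mitochondrial share was 4.74% and 10.2%. These values rest on 59 and 67 nuclei with medians of 2847 and 4104 UMIs, and over 1061 genes 12 were at least 2-fold higher and 10 lower, which is 54.5% higher, against 42.9% (9 and 12) with TMM and 33.3% (7 and 14) with mitochondrial genes in the total.

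Chromatin accessibility was compared over 113805 regions with a peak in both accessibility libraries. In tumour-cell-like nuclei, the region at the Cask gene end on chromosome X (13846308 to 13847172) had 1906 counts in Sun1_WT and 20 in Sun1_KO, a log2 ratio of -5.96 (-6.71 to -5.37). A region at Prkx (X, 77795571 to 77796464) had 1681 and 40 counts (-4.80, -5.31 to -4.37), and a region at Gas7, a growth-arrest gene (chromosome 11, 67521799 to 67523170), had 661 and 15 (-4.84, -5.73 to -4.15). A region near Nyx (X, 13461324 to 13462248) was at -4.70 and a region on chromosome X from 134612149 to 134613071, near no annotated gene end, at -5.05. Among the 5 highest, 1 region lay at Arhgap15 (chromosome 2, 43806038 to 43806950; 2.69, 2.40 to 3.01) and 2 lay at Cdh18, a cadherin gene (chromosome 15, 23451871 to 23452792 and 23419689 to 23420568; 2.68 and 2.61). The others lay on chromosome 11 (6679782 to 6680878; 45 and 243 counts) and chromosome 1 (69755412 to 69756353; 2.65). Of 108098 regions, 1682 were at least 2-fold higher and 1520 lower (52.5% higher), and with binarised counts 1384 were higher and 620 lower (69.1%). At Ift81 the regions over the gene were at -0.07, beside 2.91 in RNA, and at Ccl2 they were at -1.73, beside -3.47 in RNA, both chosen after their values were seen.

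In macrophage-like nuclei, 108 of 36669 regions were at least 2-fold higher and 185 lower (36.9% higher), and with median-ratio scaling 141 were higher and 126 lower. A region at Ifi202b, an interferon-inducible gene (chromosome 1, 173960901 to 173961877), had 48 and 262 counts (2.37, 1.93 to 2.86). Regions at Tent4b, an RNA-tailing enzyme gene (chromosome 8, 88228301 to 88229109), and Abr (chromosome 11, 76469400 to 76470306) were at -1.88 and -1.64. Regions at Tyk2 (1.85) and Zbtb16 (1.99) stood at -0.47 and -2.63 when peaks had to overlap by at least 0.5 of each. NK-cell-like nuclei had 59 higher and 167 lower of 18056 regions, including a region at the apoptosis gene Bcl2l11 (chromosome 2, 128152685 to 128153942) at -2.29 (-3.11 to -1.60) and a region at Bcl11b (chromosome 12, 107992708 to 107993622) at 1.85 (1.17 to 2.63). T-cell-like nuclei had 42 higher and 54 lower of 10875. Across 9899 genes in tumour-cell-like nuclei, accessibility near gene ends correlated with RNA at r = 0.38 (rho = 0.23), and 76.4% of the 331 of them at least 2-fold apart in RNA lay on the same side. Across genes, r was 0.08 (rho = 0.05) in macrophage-like nuclei, 0.05 (rho = 0.03) in NK-cell-like and 0.12 (rho = 0.09) in T-cell-like nuclei, and genes are not independent replicates.

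Counts were then compared by chromosome, since injected cell populations can differ in copy number. A stretch of chromosome X between 5 and 45 Mb, which holds Cask and Il13ra1, was lower in Sun1_KO tumour-cell-like nuclei in both assays. Accessibility counts there were 588999 and 229322, a log2 ratio of -0.79 (-0.79 to -0.78), and 95.4% of its 539 regions were below 0 with a median of -0.78, against 0.03 over the other 2011 regions of the chromosome. In RNA, 79 of its 86 genes were below 0 with a median of -0.57, against 0.26 over the other 266 genes. In host cells the accessibility of the stretch was at -0.10 in macrophage-like, 0.04 in NK-cell-like and -0.08 in T-cell-like nuclei. On chromosome 15, the stretch from 78 to 86 Mb was at -0.40 in accessibility and -0.28 in the median of 97 genes in tumour-cell-like nuclei, against -0.06 in accessibility in macrophage-like nuclei. Both boundaries were chosen after seeing the data. Of 1234 windows of 2 Mb, 35 were at or below -0.3 in tumour-cell-like nuclei, among them 13 of the 13 windows of the X stretch, and 34 were at or above 0.3, while in macrophage-like nuclei 0 of 1026 windows were at or below -0.3 and 6 at or above 0.3.

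Nuclei of the Sun1_WT tumour were not uniform in this stretch. Among 1865 Sun1_WT tumour-cell-like nuclei with at least 5000 accessibility counts, 451 (24.2%, 22.3 to 26.2) had less than 3000 CPM of their accessibility counts in it, with a median of 2265 against 4389 in the others. In Sun1_KO, 988 of 1005 nuclei (98.3%) were below 3000, with a median of 2157. In macrophage-like nuclei 6.36% and 4.22% were below it. The boundary was chosen after seeing the data, and 86 Sun1_WT and 35 Sun1_KO tumour-cell-like nuclei lay between 2700 and 3300. Against the low-share Sun1_WT nuclei alone, 237 genes were at least 2-fold higher and 192 lower in Sun1_KO tumour-cell-like nuclei, Cask stood at -6.01 and Ift81 at 2.88, and Sun1 at -0.68 (-0.80 to -0.55).

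**Figure D3:**
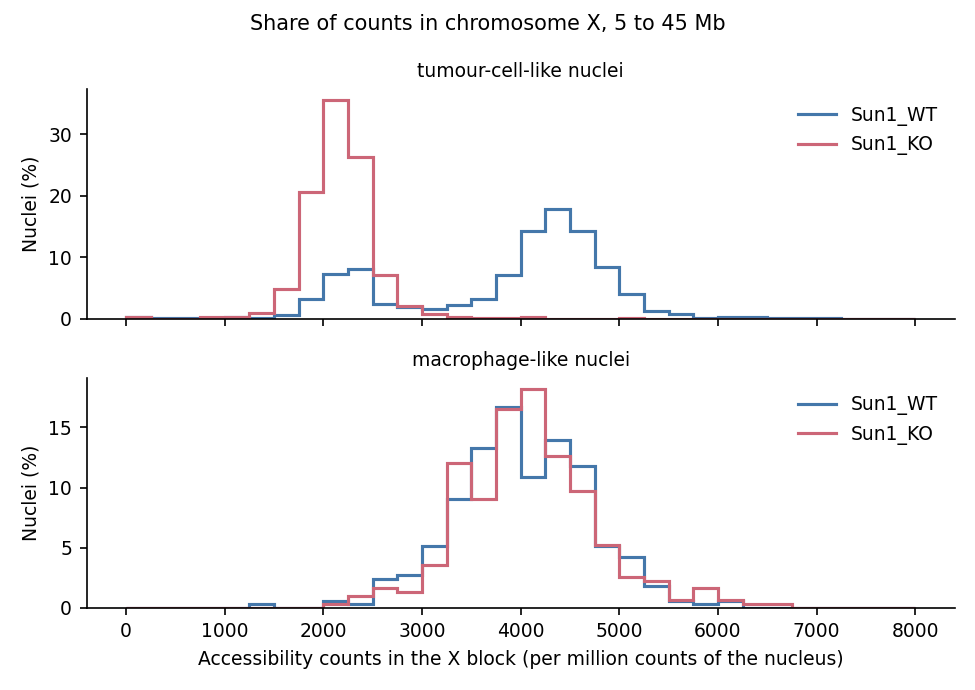
Distribution of tumour-cell-like and macrophage-like nuclei (y axis, % of nuclei) by the share of their accessibility counts that falls in chromosome X from 5 to 45 Mb (x axis, CPM), for each library. Sun1_WT tumour-cell-like nuclei form a large group around 4389 and a smaller one around 2265 CPM, where Sun1_KO nuclei also lie (2157).

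The authors' deposited table lists 10156 genes with DESeq2 fold changes, and its direction, read here against the counts, is Sun1_KO over Sun1_WT. Of the genes in the authors' deposited table, 9042 had an adjusted p under 0.05 by the Wald test, with 8624 higher and 418 lower and a median log2 fold change of 0.59. With 1 expression library per genotype there were no replicate tumours, so these adjusted p-values do not measure variation between tumours. Ift81 (3.20), Ikzf2 (2.21), the thyroid hormone deiodinase gene Dio2 (2.14) and Csmd3 (1.99) were among the 10 highest of the authors' deposited table, and Ccl2 (-1.81), the surface antigen gene Ly6c1 (-1.74), the histone methyltransferase gene Nsd1 (-1.62) and Cask (-1.37) among the 10 lowest. Sun1 stood at -0.35 in the authors' deposited table. Across 10143 genes, the fold changes of the authors' deposited table correlated with the ratios over all kept nuclei at r = 0.85 (rho = 0.92), and theirs were higher by a median of 0.44. Of the 418 lower genes of the authors' deposited table, 18 (4.31%) lay in the X stretch, against 71 of all 10156 (0.699%). Which nuclei entered the authors' deposited table and how it was scaled are not given in the sources used here.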

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

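Of the tests below, those on regulated peaks, on open ribosomal protein genes, on free granzyme RNA and on a handful of nuclei were written before their values were seen. The others were chosen after seeing the result.

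The lower stretch of chromosome X in Sun1_KO tumour-cell-like nuclei was tested for 3 explanations. Library size, scaling or mapping would have lowered it in macrophage-like nuclei too, where accessibility was at -0.10. A few strongly regulated peaks would have left the typical region near 0, but the median region was at -0.78. Fewer copies of the stretch in the injected Sun1_KO cells stays open. Its lower RNA, with the median gene at -0.57, is part of the pattern and so lends that explanation no support, and DNA copy number was not measured.

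The lower ribosomal protein RNA, with the higher mitochondrial share, was also tested for 3 explanations. Loss of Sun1 acting only inside tumour cells would leave macrophage-like nuclei near 0 if they held no tumour RNA, and the median there was -0.46. The tumour gene Hmga2 was at 84.7 CPM in Sun1_WT and 226 CPM in Sun1_KO in that class, against 3045 and 4705 CPM in tumour-cell-like nuclei. In NK-cell-like nuclei it was at 48.6 and 52.7 CPM, and the ribosomal protein median was -0.75 (-0.86 to -0.68). By this 1 gene, tumour RNA was scarce in these host classes, which argues against this explanation for the ribosomal protein genes. Tumour RNA that Hmga2 does not track was not measured, so the explanation is not excluded. Less open ribosomal protein genes would show in accessibility, which had a median of -0.013 over 26 genes. A difference of the whole library, in nuclei preparation or free RNA, stays open, since the host medians are part of the pattern. The highest of them, -0.31 in T-cell-like nuclei, lay at percentile 9.62 of random lists, whose own median was -0.15. Some other transcripts also differed in edited and host classes alike. In tumour-cell-like, macrophage-like, NK-cell-like and T-cell-like nuclei, Gm42418 was at 1.25, 1.00, 1.25 and 0.91, and Lars2 at 1.40, 1.11, 1.06 and 0.82. Malat1 was at -0.44, -0.47, -0.06 and -0.75 there. These genes were picked from many, so they do not settle the cause.

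For the higher granzymes D to G in Sun1_KO NK-cell-like nuclei, reads moved only among these 4 near-identical genes would leave their sum unchanged, but its log2 ratio was 3.42, as already followed from each of the 4 being higher. Free RNA would put them in macrophage-like nuclei, where they reached 0.0701% of the NK-cell-like level. A handful of nuclei would hold most of the UMIs, and 5 nuclei held 100% of them, which is consistent with it. Of these, 1 nucleus held 99.5%. The log2 ratio of the sum without it, but with all Sun1_WT nuclei kept, was -3.98, which is lower by construction. That nucleus had 25005 UMIs in all, with 16 of Ptprc and 1 of Hmga2.

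Other values stood apart without a test. Peaks without a partner in the other library, left out of the comparison of regions, held 1.79% of Sun1_WT and 2.51% of Sun1_KO accessibility counts over all nuclei. The totals that regions of a class were divided by include these peaks, and their share by class was not computed. In macrophage-like nuclei every chromosome from 1 to 19 and X was below 0 in accessibility, from -0.08 (chromosome 4) to -0.04 (chromosome 1). G2/M genes had medians of 0.26 in macrophage-like, -0.36 in NK-cell-like and 0.35 in T-cell-like nuclei, and over nuclei with no Hmga2 UMI the first was 0.11 (-0.036 to 0.19). MHC class II genes had medians of -0.46 in tumour-cell-like and 0.29 in macrophage-like nuclei, the latter 0.095 over nuclei with no Hmga2 UMI, and against only the low-share Sun1_WT nuclei the former was 0.205, on the same side of 0 as the latter. The log2 ratio of the X stretch was lower in tumour-cell-like than in NK-cell-like nuclei by a difference of -0.83. Sun1 was at 0.24, 0.21 and 0.70 in macrophage-like, NK-cell-like and T-cell-like nuclei, on the other side of 0 from tumour-cell-like nuclei, with intervals that include 0.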

How the results depend on the processing

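Another scaling shifts every gene of a class alike, and TMM moved the median tumour-cell-like gene from 0.14 to -0.08. A list above 0 by less than that shift falls below 0, whether or not it is named here, and a list below 0 moves further down. With TMM scaling the medians were -0.12 for G2/M, -0.17 for nuclear envelope, -0.17 for type I interferon, -0.0017 for NF-kB and -0.039 for checkpoint genes, Sun1 was at -0.94, and 144 genes were at least 2-fold higher and 681 lower. With median-ratio scaling they were -0.038 for G2/M, -0.087 for nuclear envelope and -0.088 for type I interferon genes, Sun1 was at -0.86, and 186 genes were higher and 536 lower. In NK-cell-like nuclei 22 genes were higher with it. With mitochondrial genes in the total, nuclear envelope and type I interferon genes were at -0.020 and -0.021 in tumour-cell-like nuclei, and 7 genes were higher in T-cell-like nuclei.

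Counts of genes past 2-fold followed the UMI minimum. With at least 20 summed UMIs, 1008 genes were higher and 659 lower in tumour-cell-like, 337 and 277 in macrophage-like, 319 and 311 in NK-cell-like, and 273 and 209 in T-cell-like nuclei. With at least 500, these were 69 and 179, 7 and 12, 5 and 17, and 0 and 1, and the correlation with the authors' deposited table was 0.873. A pseudocount of 5 left 6 higher genes in T-cell-like nuclei.

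Thinned to 1000 UMIs per nucleus, tumour-cell-like nuclei had 57 higher and 107 lower genes, Sun1 at -0.55, Car9 at -0.30, and medians of 0.0016 for MHC class I, 0.038 for S phase and -0.053 for checkpoint genes. Macrophage-like nuclei had 6 higher and 16 lower genes, Sun1 at -0.40, Slit3 at -0.39 and Ckap2 at -0.67. NK-cell-like nuclei had 5 and 25, with Itgb3 at -0.54, and T-cell-like nuclei 0 and 3, with Eno1 at 0.33 and Rpl3 at -0.028. The cause was not tested, and few UMIs remain after thinning.

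Filters on nuclei, for the shares together with new clustering, mattered most for shares and for NK-cell-like granzymes. The ratio of tumour-cell-like shares was 0.978 over nuclei with at least 1500 UMIs and 1.07 without the top 5% of doublet scores, added after seeing the data. The kept nuclei were clustered and named again in both runs, so the filter alone is not shown to move that ratio. Over nuclei with no Hmga2 UMI, also added, Gzmd, Gzme, Gzmf and Gzmg were at -2.52, -2.58, -6.53 and -3.12 in NK-cell-like nuclei, Slit3 was at -0.74 in macrophage-like nuclei, and 28 genes were higher there. Without 1 Sun1_KO nucleus, added, the same granzymes were at -2.55, -2.66, -6.99 and -3.14. Without the nucleus of each library with most UMIs of the gene, added, they were at -1.96, -2.18, -6.58 and -2.53. In these 3 settings Gzmg had 0 Sun1_KO UMIs, so its values come from the added 0.5 alone and its intervals reach above 0 (upper limits 0.46, 0.44 and 1.55). Against only the low-share Sun1_WT nuclei, added, the MHC class II median in tumour-cell-like nuclei was 0.205 and 192 genes were lower.

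In accessibility, a minimum of 50 counts gave 640 higher and 713 lower macrophage-like regions. Binarised counts gave 6 and 3, and 1384 higher and 620 lower regions in tumour-cell-like nuclei. With an overlap of at least 0.5 of each peak, the macrophage-like regions at Tyk2 and Zbtb16 were at -0.47 and -2.63. Without the 1% of features with most counts, chromosome X in tumour-cell-like nuclei was at -0.13 in RNA and -0.13 in accessibility, against -0.22 and -0.13 with all features.

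Over all alternatives, named genes kept their value 2048 times, moved 233 times and changed side 19 times, and list medians 356, 77 and 14 times. A change of side was counted only where the interval of the first value left out 0, so the tumour-cell-like mesenchymal, macrophage-like pro-inflammatory and T-cell-like exhaustion medians, which passed 0 in some runs, are not among the 14. Keeping called doublets gave nothing new, since no nucleus had been removed. The filter on Krt8 and Krt18 UMIs removed no host nucleus and so tested nothing there. At resolution 0.5 macrophage-like and NK-cell-like nuclei had no named cluster, and with each library clustered on its own T-cell-like nuclei gave no ratio either. The ratio of tumour-cell-like shares was 0.802 and 0.792 in these runs. No paired analysis was possible because each genotype had 1 library and nothing but the replicate number 1 links them.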

Other observations

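Ccl2 and Nsd1 were concentrated in a part of the Sun1_WT tumour-cell-like nuclei. Nsd1, a histone H3 lysine 36 methyltransferase gene chosen after its values were seen, stood at -2.27 in this class. It was found in 42.1% of Sun1_WT nuclei, where 83.9% would be met if its 4412 UMIs were spread in proportion to each nucleus's depth, and in 26.6% of Sun1_KO nuclei against 34.1%. Ccl2 was found in 34.3% against 72.4% in Sun1_WT, and in 9.54% in Sun1_KO. In macrophage-like nuclei, Nsd1 was found in 63.9% and 64.4% and Ccl2 in 45.6% and 40.9%, at median depths of 4659 and 4448.5 UMIs against 18764 and 17589 in tumour-cell-like nuclei. Accessibility over Nsd1 was at 0.18 in tumour-cell-like nuclei, beside -0.06 in macrophage-like nuclei.

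Several loci were less open or more open in Sun1_KO tumour-cell-like nuclei. All 30 regions over Gas7, a gene of actin and membrane organisation, were together at -2.90 in tumour-cell-like and 0.01 in macrophage-like nuclei. The region at Gnasas1 was at -3.43, and the region at the end of Aldh5a1 (chromosome 13, 24937147 to 24938105) at -3.84 while its other 3 regions were at -0.15. Over Cask, the 9 regions apart from its gene end were at -1.54, beside 0.22 in macrophage-like nuclei. Arhgap15 was more open over 17 regions, at 1.46, beside -0.06 in macrophage-like nuclei. Ikzf2 was at 0.79 over 2 regions, and it was also higher in macrophage-like nuclei, at 0.35 (0.12 to 0.58). These loci were chosen after their values were seen.

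The test named here was written before its value was seen. If the Sun1_KO cells descend from a subpopulation that the control cells also hold, the 10 genes named as lower would be low in the Sun1_WT nuclei with a low share of counts in the X stretch. Their median log2 ratio, low-share to other Sun1_WT nuclei, was -0.47 (from -3.98 to 0.44 by gene). Cask (-0.94) and Il13ra1 (-0.57) lie in the stretch that chose these nuclei, and over the other 8 genes, a median taken after seeing the data, it was -0.26. Tmlhe (-0.83), which was given no position, is among those 8. The 10 genes named as higher, not part of that test, had a median of 1.05 in the same comparison (from -1.65 to 2.28 by gene). Arhgap15 (1.56), Lrfn5 (1.81), Kcnab2 (2.20) and Adamts12 (2.28) had intervals above 0 and Ikzf2 (-1.45) an interval below 0. The intervals of the rest included 0. Since those 8 lower genes and the 10 higher genes each went both ways, this origin and an independent change of the X stretch cannot be told apart. Against the low-share nuclei, the median in Sun1_KO was still -5.36 over the 10 genes named as lower and -4.96 over those 8, and that of the 10 genes named as higher was 2.41. The stretch of chromosome 15 was not low in the low-share Sun1_WT nuclei (10037 and 10039 CPM, 7569 in Sun1_KO). Several independent Sun1_KO and control clones, with DNA copy number measured before injection, could separate effects of Sun1 loss from differences between clones.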
